A study of Mus musculus with 2 samples.

How the data were processed

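PolyA-selected RNA from G1E-ER4 cells after 14 h in estradiol was measured in 2 libraries, per the labels, which number them as biological replicates 1 and 2 of 1 experiment. Per the labels the reads are paired-end and the build is mm10; the deposited notes name GENCODE M4 as the annotation. The aligner, the quantifier's version and its settings are not given in the sources used here. Per the file headers, whose column names are those of RSEM, each library has 1 table of genes and 1 of transcripts.

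The deposited expected counts are estimated fragment counts that need not be whole, because reads that match several transcripts or genes are divided among them. The deposited TPM divides expected counts by effective transcript length and scales the sum over the table to 1e6. The deposited FPKM divides them by effective length and by the number of fragments. The deposited isoform percent is a transcript's part of its gene's TPM. The deposited bounds of the TPM interval, a signal unit here, were read and are not reported. Because TPM and FPKM divide by the length of the transcripts chosen, a gene whose reads are placed on a short transcript gets a high TPM.

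The gene tables have 69691 rows. Of 43346 Ensembl gene rows, 42462 were given symbols and biotypes by identifier from GENCODE M21 on GRCm38, the same build, and 884 kept their identifier. The 26248 rows with no gene name held 2 counts in replicate 1 (5.2e-06% of the total) and 0 in replicate 2, and the 97 spike-in rows held 0 in both; these rows were left out of library sizes and tests. Transcript sequences were found for 101510 of 103639 Ensembl transcripts and used for GC content, taken from each gene's most abundant transcript. Of the 101510 sequences, 91424 had the same length as the deposited transcript, and all were used without a check on length. GC values of the rest may describe a different model. Transcript lengths given below are the deposited ones, while types, exon numbers and coordinates are those of M21. Expected counts summed to 38395481 and 60097379, so replicate 2 was 1.57 times as deep and low genes are more precise in it.

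With 1 group and no control, no test between conditions was made. Levels are given as mean ± SD of TPM, n = 2. A gene counted as expressed at 1 TPM or more in both libraries, high at 50 or more in both, and not detected under 0.1 in both. The 22 gene lists, 20 gene pairs, 38 isoform genes, the tests, the thresholds for calls, the naming rule and the alternatives were fixed before the data were examined, except where a later choice is stated. A list's median was placed among 10000 random lists of as many nuclear protein-coding genes. Its median log2 ratio of replicate 2 to replicate 1, of TPM + 1 over members with mean TPM of at least 1, was placed among 10000 lists matched in 20 bins of mean expression; lists with fewer than 3 such members were not placed. These percentiles describe the libraries and are not p-values.

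Differences between the libraries were tested per gene with an exact two-sided binomial test on expected counts rounded to whole numbers, against library sizes scaled by the TMM method of edgeR, for genes with at least 10 counts in sum. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 1.5, with 0.5 counts added to each library for the fold. On simulated data for this comparison, 74 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were called, and 0 of 11037 unchanged genes. The simulation has counting error only, so it says nothing about the spread between replicates. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design after filterByExpr, on 10207 genes; simulated values of 0.1 and 0.3 were recovered as 0.0997 and 0.295 on 10435 and 10340 genes. In simulated lists of 15 genes, 100 of 100 shifted by 1 on the log2 scale and 7 of 100 unshifted ones fell outside percentiles 2.5 to 97.5.

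Pair ratios were log2 ratios of TPM + 0.1, called larger than the spread where both libraries gave the same direction and the mean was over 2 times their range. Folds against a gene with no counts were computed against 3 counts per library and are lower bounds. Intervals of folds are exact (Clopper-Pearson, 95%) and cover counting error only. Isoforms were described for genes with mean TPM of at least 5 and 2 or more transcripts at 10% or more in both libraries. The text names the 20 nuclear protein-coding genes with the highest mean TPM other than ribosomal protein genes, the 4 highest members of each list and up to 3 that were not detected, all members of the globin and erythroid factor lists, both genes of each pair, the 5 called genes with the largest fold in each direction and mean TPM of at least 5, and the isoform genes that passed. Some genes that this rule picks are not used here. Further list members are named as examples of a group and were chosen after their values were seen.

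Alternatives covered other pseudocounts, expression and count filters, FPKM, posterior mean estimates, DESeq2 size factors, total counts, counts not divided by length, TPM without mitochondrial and globin genes, and each replicate left out. Removal of a trend with GC content from the list comparison was added after the data were seen. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.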

Results

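PolyA-selected RNA from G1E-ER4 cells was sequenced as paired ends in 2 libraries. G1E-ER4 is an immortalised mouse erythroid line made from G1E cells, which lack the transcription factor GATA1, by adding GATA1 fused to the hormone-binding domain of the estrogen receptor, so that estradiol switches the fusion protein on and starts red cell differentiation. Both libraries came from cells kept in 10 nM 17beta-estradiol for 14 h and form 1 group of 2 numbered biological replicates. The labels give both the same biosample record, so the spread between them may be partly technical. The expected counts summed to 38395481 in replicate 1 and 60097379 in replicate 2. A limit of 3 counts, the most that a count of 0 allows, equals 0.0781 CPM (counts scaled to a library of 1e6) in replicate 1 and 0.0499 in replicate 2, and covers counting error only. No untreated or earlier sample was analysed here, so the values below are levels at 14 h and differences between the replicates, not responses to estradiol. Values are TPM, transcript numbers scaled to a total of 1e6, as mean ± SD, n = 2, unless a single library is named, and coordinates are those of GRCm38.

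The first question was which erythroid genes the cells expressed. The adult globins were among the most abundant messages and the embryonic globins were close to the detection limit. Hbb-bs, an adult beta globin (chromosome 7, 103826534 to 103828096), stood at 31405 ± 25805 TPM, with 13158 in replicate 1 and 49652 in replicate 2. Of this TPM, 98.2% and 99.9% lay on a short transcript annotated as retained intron, so the level depends on that assignment. The adult alpha globins Hba-a1 (chromosome 11, 32283511 to 32284465) and Hba-a2 (chromosome 11, 32296489 to 32297298) stood at 14073 ± 9837 and 9734 ± 274 TPM. The other adult beta globin, Hbb-bt, stood at 220.3 ± 269 TPM. Its counts were not whole, a sign of shared reads, and Hbb-bs over Hbb-bt went from 442 to 121 by TPM. The sum of both was 31625 ± 26074 TPM. Of the embryonic genes, Hba-x had 0.625 ± 0.46 TPM, Hbb-bh1 1.24 ± 1.24 TPM and Hbb-y 0.11 ± 0.156 TPM, the last from 0 and 6 expected counts. Hbq1b had 1.51 ± 1.56 TPM, and Hbb-bh0, Hbb-bh2 and Hbq1a had 0 counts in both libraries. Adult alpha and beta globin TPM exceeded the summed embryonic TPM by a factor of 9880.1 in replicate 1 and 91627 in replicate 2. The ratio of beta to alpha globin was not stable, at 0.774 in replicate 1 and 1.64 in replicate 2. Hba-a1 and Hba-a2 are near-identical copies that share reads, and their ratio went from 0.717 to 2.2 between the libraries, so the sum of 23807 ± 9563 TPM is the safer value. Ahsp, Hbb-b1 and Hbb-b2 were not analysed here.

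Nearly the whole erythroid regulatory set was expressed. Of the 21 transcription factors and cofactors on the fixed list, 20 reached 1 TPM in both libraries and 17 reached 50 TPM. The highest was Zfpm1, which encodes the GATA1 partner FOG1, at 3136 ± 1336 TPM (chromosome 8, 122282141 to 122337251). Gata1 itself stood at 1894 ± 1077 TPM, a value that does not separate the added GATA1 from the gene's own locus, Lmo2 at 1674 ± 1003, Klf1 at 1088 ± 472, Ldb1 at 702 ± 243 and Tcf3 at 600.3 ± 232 TPM. LMO2, LDB1, TAL1 and TCF3 are known to bind DNA together with GATA1, and Tal1 stood at 287 ± 59 TPM. The repressor Gfi1b stood at 368 TPM in replicate 1 and 652 in replicate 2, and the corepressor Cbfa2t3 at 273 ± 103 TPM. Foxo3 had 219.97 ± 100.2 TPM, Mafk 188 ± 24, Klf3 145 ± 28.3, Nfe2 141 ± 29.5 and Zbtb7a 135 ± 32.9 TPM. Bcl11a, a repressor of embryonic and fetal globins, had 74.5 ± 1.46 TPM, Tcf12 72.6 ± 28.6 and Mafg 71.1 ± 3.02 TPM. Lyl1, Bach1 and Lmo4 were lower, at 26 ± 2.05, 25.4 ± 1.54 and 6.79 ± 1.89 TPM. Sox6 was the exception on the list, with 0.095 ± 0.00707 TPM from 7 and 20 counts. The list median was 188 TPM. Random lists of as many nuclear protein-coding genes had a median of 0.03 TPM, so the place of this list above all of them says only that its members were expressed, as it does for the housekeeping list.

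Haem synthesis genes were expressed as a group. All 12 list members passed 1 TPM in both libraries and 8 passed 50 TPM, with a median of 209 TPM. Alad, which joins 5-aminolevulinate into porphobilinogen, stood at 760.2 ± 313 TPM, Tmem14c, a porphyrin transporter, at 499.5 ± 535, the mitochondrial transporter Abcb10 at 376 ± 82.9 and Cpox at 369.7 ± 35.1 TPM. Alas2, the erythroid form of the first and rate-limiting enzyme, was lower at 41.8 ± 32.7 TPM, and Uros was the lowest at 9.26 ± 2.96 TPM. 7 of the 12 genes differed between the libraries, all with more scaled counts in replicate 2, in an exact two-sided binomial test with Benjamini-Hochberg adjustment and a fold minimum of 1.5, and 7 when adjusted over the list alone. Of all 11230 tested genes 40.9% were called in this way, the share against which this and later list counts stand. Tmem14c was 7.22-fold higher in replicate 2, Urod 3.97-fold, Abcb6 3.84-fold and Alas2 3.48-fold by TPM; by scaled counts not divided by length these were 7.73-, 2.19-, 4.13- and 1.83-fold. Slc25a38 was higher in replicate 2 by counts only, with 209 and 198 TPM. The median log2 ratio of replicate 2 to replicate 1 over the list was 0.53, at percentile 99.3 of random lists matched on expression.

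Iron storage messages were at globin-like levels. The ferritin chains Ftl1 (chromosome 7, 45457944 to 45459884) and Fth1 (chromosome 19, 9980598 to 9985098) stood at 16631 ± 3340.5 and 14323 ± 5613 TPM. The RNA-binding iron chaperone Pcbp1 had 1928 ± 1086 TPM and the mitochondrial glutaredoxin Glrx5 1558 ± 301 TPM. The transferrin receptor Tfrc was far below them at 19.5 ± 3.44 TPM, and the mitochondrial iron importer Slc25a37 stood at 149 ± 7.11 TPM. Tfrc had 38.1% GC, against 53.4% for Fth1, 57.8% for Pcbp1 and 53% for Glrx5. Genes with less GC were less often above 50 TPM, as given below, so the low place of Tfrc was not separated from GC content. The largest part of Tfrc, by mean share, also lay on a transcript annotated as retained intron. Of the 17 iron genes, 16 were expressed, and only Hfe, with 0.085 ± 0.0212 TPM, stayed under 1 TPM. Ftl1 and Fth1 have processed copies in the genome that can share their reads.

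Red cell membrane genes were expressed unevenly. The skeleton genes Sptb (beta spectrin), Add1, Ank1 and Add2 stood at 711 ± 40.9, 673 ± 104, 333 ± 11.8 and 270.2 ± 73.1 TPM. Protein 4.2 (Epb42) had only 0.735 ± 0.0919 TPM, and the anion exchanger Slc4a1 30.4 ± 9.44 TPM. The water channel gene Aqp1 was not detected, at 0.05 TPM in replicate 1 and 0.05 in replicate 2. Altogether 20 of 22 members were expressed and 10 were above 50 TPM. 8 of the 22 members differed between the libraries in the exact binomial test (8 when adjusted over the list alone), of which 7 were higher in replicate 2, such as Icam4 at 21.8 against 132 TPM. This count is no larger a share than the 40.9% called among all tested genes. The list median was 30.3 TPM in replicate 1 and 59.7 TPM in replicate 2.

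Genes of late maturation and redox defence were mostly present. Biliverdin reductase Blvrb had 2551 ± 667 TPM, the glutathione peroxidase Gpx4 1969.6 ± 291, carbonic anhydrase Car2 665 ± 318 and hexokinase Hk1 629.8 ± 78.8 TPM. Trim58, a ubiquitin ligase of late erythroblasts, and Alox15, a lipoxygenase of reticulocytes, were not detected, with 0.02 ± 0 TPM for Trim58 and 0 counts for Alox15. 18 of 21 measured members were expressed. This list had the highest percentile toward replicate 2 among the 16 lists compared, with a median log2 ratio of 0.54 at percentile 99.8 of matched lists. With members of at least 5 TPM only, it stood at percentile 98.9, below S phase (99.6), globins (99.5) and haem synthesis (99.3). 11 of its 19 tested genes had more scaled counts in replicate 2 by the exact binomial test, Cat by counts only (202 and 190.1 TPM), and 1, Car1, was higher in replicate 1, with the same total of 12 when adjusted over the list alone. The median TPM of the list went the other way, at 60.6 in replicate 1, where Car1 is the middle gene, and 28.6 in replicate 2.

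The next question was whether progenitor or other lineage genes were expressed. Progenitor genes ranged from high to undetected. Hhex stood at 418 ± 267 TPM, Myc at 388 ± 25.2, Runx1 at 240.2 ± 83.4 and Gata2 at 98.4 ± 43.8 TPM, and Kit at 11.8 ± 2.44, Myb at 6 ± 0.262, Meis1 at 2.25 ± 0.502 and Erg at 1.91 ± 0.198 TPM. Hoxa9, with 0 counts in both libraries, and Cd34 and Flt3, with at most 1 count in a library, were not detected, as were 8 of the 16 members in all. Some megakaryocyte genes were expressed at low levels, led by Gp1ba at 52.3 ± 6.39 TPM, Gp5 at 17.5 ± 5.03, Fli1 at 15.1 ± 2.32 and Itga2b at 5.46 ± 0.884 TPM. 7 of 16 megakaryocyte markers passed 1 TPM, none reached 50 in both libraries, and Gp1bb and Ppbp were not detected.

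Markers of other blood and non-blood cells were near 0. Of 17 granulocyte and macrophage markers, the only 2 above 1 TPM were Spi1, which encodes the factor PU.1, at 21 ± 1.8 TPM and Cd68 at 1.14 ± 0.0849 TPM. Prtn3 followed at 0.42 ± 0.325 TPM, and Mpo, Elane and Ctsg were not detected. Among mast cell and basophil markers Hdc passed 1 TPM in both libraries, at 2.1 ± 0.601 TPM, and Srgn in replicate 2 alone (0.69 and 4.84 TPM). Fcer1a and Cma1 stood at 0.075 ± 0.106 and 0.07 ± 0.099 TPM, and Cpa3, Mcpt4 and Mcpt8 were at 0 counts. No lymphoid marker passed 1 TPM in both libraries. Lck was the highest at 0.775 ± 0.884 TPM, Ebf1 had 0.155 ± 0.219 TPM, Cd79a 0.105 ± 0.0778 and Cd79b 0.045 ± 0.0636 TPM, and Pax5 had 0 counts. All 13 pluripotency genes were under 0.1 TPM, with Pou5f1, Nanog and Sox2 at 0 counts and Esrrb the highest at 0.005 ± 0.00707 TPM. Of 13 fibroblast and endothelial markers, 12 were under 0.1 TPM in both libraries, among them Col1a1, Col3a1, Kdr and Pdgfra. The exception was Col1a2 at 0.065 ± 0.0778 TPM.

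**Figure D1:**
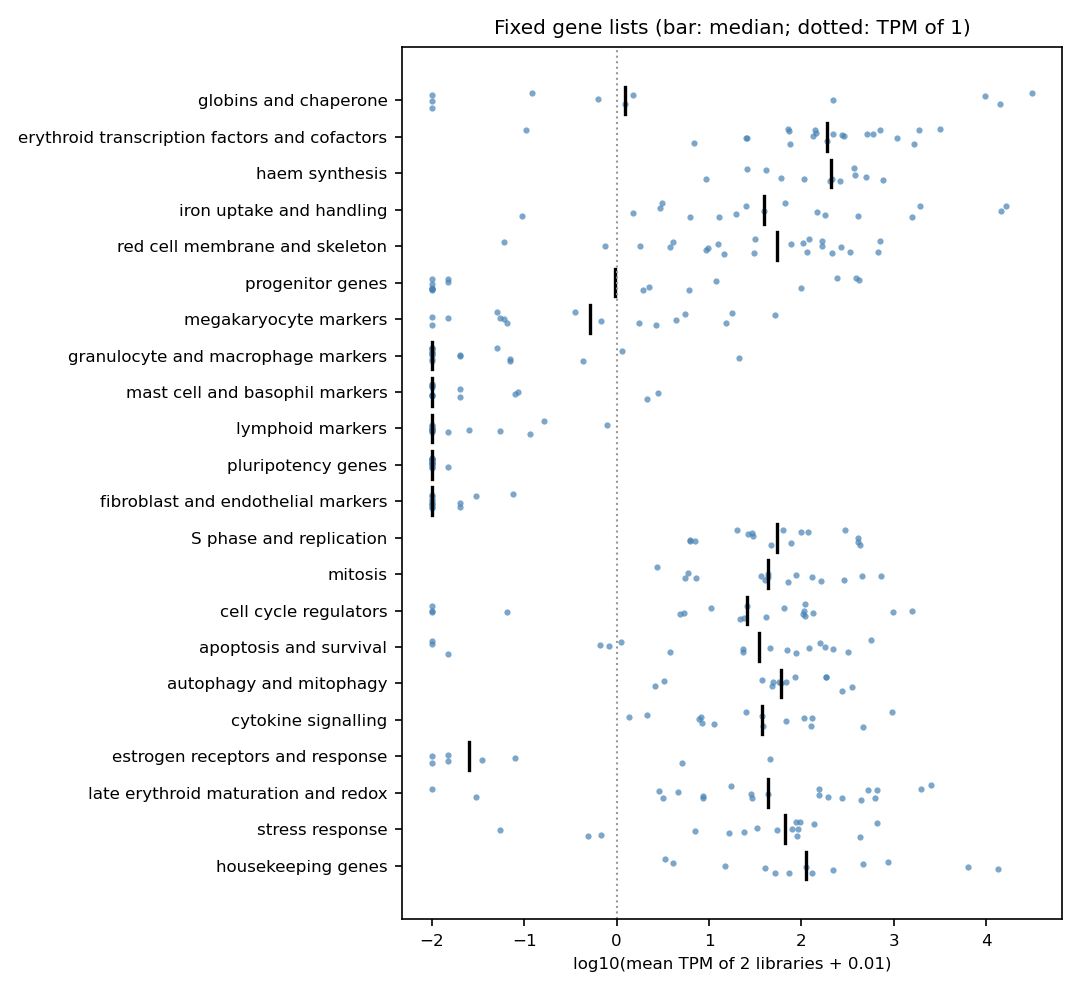
Mean TPM of the members of each fixed list, as log10(mean TPM + 0.01), with one point per gene, a black bar at the list median and a dotted line at 1 TPM. Erythroid factor, haem, iron, cell cycle and housekeeping lists lie mostly right of the line, and the lymphoid, pluripotency and fibroblast lists lie left of it.

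The cells expressed the full set of replication and mitosis genes. All 16 S phase genes and all 15 mitosis genes passed 1 TPM in both libraries. Cyclin E1 (Ccne1) stood at 429 ± 304 TPM, the ribonucleotide reductase subunit Rrm2 at 409.7 ± 243, Mcm2 at 408 ± 95.3 and Cdt1 at 298 ± 96.4 TPM. Of the mitosis genes, cyclin A2 (Ccna2) stood at 719 ± 262 TPM, Cdc20 at 456 ± 131, Aurkb at 287 ± 21.3 and Plk1 at 164 ± 50.9 TPM. Among cell cycle regulators cyclin D3 (Ccnd3) stood at 1590.3 ± 157 TPM and Cdk4 at 979 ± 323, followed by the inhibitor Cdkn2c at 134 ± 51.4 and E2f2 at 109 ± 22.3 TPM. Ccnd1, Cdkn2a and Cdkn2b had 0 counts in both libraries. The libraries differed in the S phase list, where 8 genes were higher in replicate 2 and 1, Ccne1, was higher in replicate 1, by the exact binomial test, with a total of 9 when adjusted over the list alone. The list's median log2 ratio was 0.47, at percentile 99.4 of matched lists, and at percentile 93.8 once a trend with GC content was removed. The mitosis list had a median log2 ratio of -0.15 by TPM (percentile 53.6) and 0.56 by scaled counts (percentile 99.3), so its direction depended on the unit.

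Survival and mitophagy genes were expressed, and the death receptor gene Fas was not detected. Mcl1 stood at 572 ± 372 TPM, Bax at 323 ± 124, the p53 target Bbc3 at 222 ± 188 and Bcl2l1, which encodes BCL-XL, at 179 ± 38.9 TPM. Pmaip1, Casp8 and Fas were not detected, with at most 1 count in a library. Mcl1 and Bbc3 were 2.71-fold and 4-fold higher in replicate 1 by TPM, and by scaled counts replicate 2 had 0.388 and 0.408 times the level of replicate 1. All 13 autophagy genes passed 1 TPM, led by Bnip3 at 356 ± 50.1, Gabarap at 278 ± 14.5, Becn1 at 185 ± 17.6 and Sqstm1 at 185 ± 50.9 TPM. Among cytokine signalling genes the shared beta receptor Csf2rb stood at 949 ± 369 TPM, the kinase Pim1 at 464 ± 278, Cish at 129 ± 29.9 and the erythropoietin receptor Epor at 128 ± 16.8 TPM. Esr1, the mouse estrogen receptor alpha gene, had 0 counts in both libraries, and Esr2 and Gper1 had at most 3 counts. Of that list only Esrra, an orphan receptor, and the corepressor Nrip1 passed 1 TPM, at 45.2 ± 22.4 and 5.13 ± 1.05 TPM, and Greb1, a known estrogen target, had 0.07 ± 0.0707 TPM. Stress genes were led by Hspa8 at 655 ± 269, Ppp1r15a at 428 ± 64.9, Hsp90aa1 at 138 ± 113 and Atf4 at 96.1 ± 24 TPM, and Hspa1a was not detected at 0.045 ± 0.0212 TPM. Housekeeping genes were led by Gapdh at 13450.4 ± 15868, Rpl13a at 6351 ± 316, Actb at 856 ± 747 and Eef1a1 at 466 ± 295 TPM. They were not steady references here: by the exact binomial test 10 of 13 differed between the libraries, and 10 when adjusted over the list alone.

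Pairs of genes that mark alternative states were then compared within each library. The first gene was the higher of the pair in most cases. Gata1 exceeded Spi1 by 6.36 ± 0.99 (SD, n = 2) on the log2 scale, Klf1 exceeded Fli1 by 6.10 ± 0.87, and Epor exceeded Kit by 3.44 ± 0.11. Gata1 TPM does not separate the added GATA1 from the gene's own locus. Its ratios to Spi1 and Gata2 are therefore not read as a cell state. Alas2 exceeded Alas1, the housekeeping form, by 3.76 ± 0.70, Bcl2l1 exceeded Bcl2 by 7.23 ± 0.04, and Tal1 exceeded Lyl1 by 3.45 ± 0.41. Cdk4 exceeded Cdk6 by 7.51 ± 1.06 and Ccnd3 exceeded Ccnd2 by 5.26 ± 0.38. Ccnd1 and Zfpm2 had no counts, so Ccnd3 counts were at least 30915-fold and Zfpm1 counts at least 126123-fold higher in the library with the smaller bound. Hk1 exceeded Hk2 by 5.54 ± 0.27, Slc25a37 exceeded Slc25a28 by 1.94 ± 0.11, and the glucose transporter Slc2a1 exceeded Slc2a3 by 0.97 ± 0.18, which fell to 0.34 in counts not divided by length and no longer met the criterion below. In the opposite sense Stat5a was below Stat5b (-2.58 ± 0.27) and Bnip3l below Bnip3 (-2.15 ± 0.48), the latter by TPM only, since counts not divided by length gave -0.05.

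In 15 of the 20 pairs the ratio had the same direction in both libraries and a mean over 2 times the range between them. The 5 others did not pass. Gata1 exceeded Gata2 in both libraries, by 3.13 and 5.30, and Car2 exceeded Car1 by 2.86 and 5.02, with ranges too wide for the criterion. Zbtb7a against Bcl11a (0.83 ± 0.33), Ftl1 against Fth1 (0.26 ± 0.29) and Cdkn1b against Cdkn1a (-0.10 ± 0.43) were within or near the spread. In counts not divided by length Cdkn1b over Cdkn1a turned to 1.5 and Zbtb7a over Bcl11a rose to 1.59, and these pairs and Car2/Car1 then passed. Several other ratios were smaller in those counts, at 4.91 for Klf1 over Fli1, 1.88 for Epor over Kit, 4.93 for Cdk4 over Cdk6, 3.58 for Ccnd3 over Ccnd2 and 6.04 for Bcl2l1 over Bcl2. In these pairs the lower gene was also the one with less GC, such as Fli1 at 44.5% against 61% for Klf1 and Kit at 48.2% against 59.6% for Epor, while Spi1 and Lyl1 had more GC than their partners. Among nuclear protein-coding genes the share above 50 TPM rose from 1.43% in the fifth with least GC to 21.6% in that with most, and the ratios were not separated from this. The fixed plan held no test of these ratios, and an exact sign test with n = 2 cannot go below p = 0.5.

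**Figure D2:**
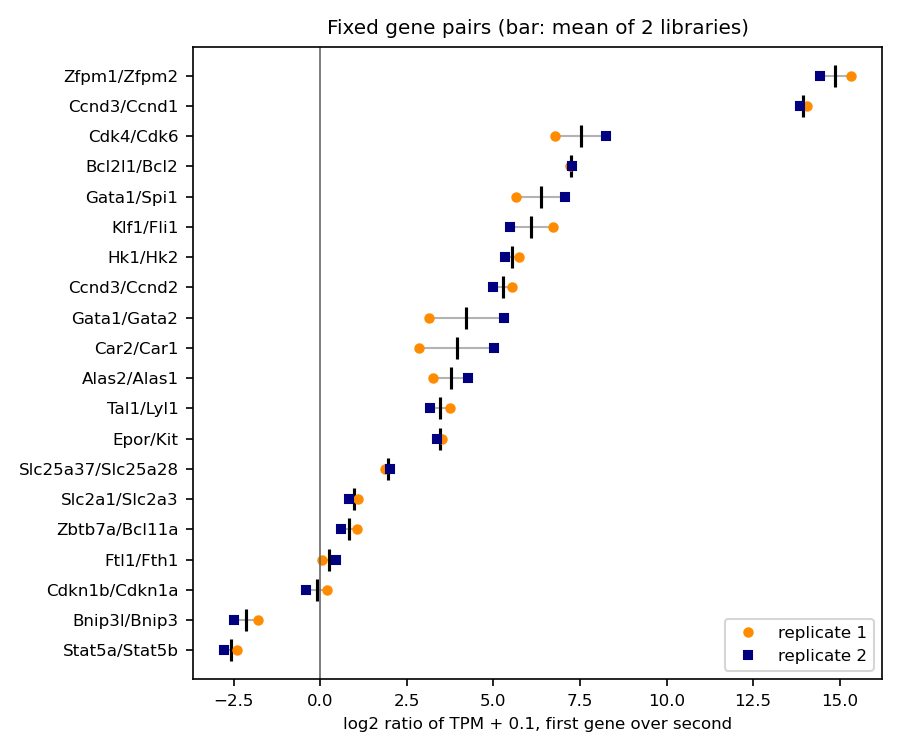
Log2 ratio of TPM + 0.1 for the fixed gene pairs, first gene over second, with a circle for replicate 1, a square for replicate 2 and a bar at their mean. The Zfpm2 and Ccnd1 ratios, at the top, rest on the added 0.1 because those genes had 0 counts, and the widest gaps between libraries are those of Gata1/Gata2 and Car2/Car1.

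Isoform use was compared for the 36 of 38 fixed genes with a mean of at least 5 TPM, of which 14 had at least 2 transcripts holding 10% or more of the gene's TPM in both libraries. Gata1, Klf1, Epor and Fech were each carried by a single transcript. The main transcript of Gata1 held at least 99.9% of its TPM in each library. Reads of the added GATA1 were not separated in this share. Tal1 was divided between the 2894-base Tal1-204 (48.1% ± 14.4) and the 683-base Tal1-202 (48.4% ± 13.8). Ldb1-202 held 59.3% ± 3.37 of Ldb1, and Tcf3-202 32.4% ± 0.672 of Tcf3. Ank1-207, an ankyrin transcript of 44 exons, held 47.1% ± 7.25. Stat5a-203 held 66.5% ± 10.5, the main transcript of Slc11a2, by mean share, 51.3% ± 5.12, Cbfa2t3-203 38.1% ± 15 and Uros-204 36.3% ± 20.8.

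Several shares moved far between the libraries or sat on short or non-coding transcripts. The 11-exon Alas2 transcript of 2037 bases held 60.4% of Alas2 in replicate 1 and 15.1% in replicate 2, while the 569-base Alas2-204, annotated as a processed transcript, went from 0% to 67.7%. Lmo2-206 held 75.1% and 22.5% of Lmo2. The largest part of Slc25a37 (60.3% ± 3.71) and of Mpp1 (55.1% ± 9.69) lay on transcripts annotated for nonsense-mediated decay, that of Tfrc, by mean share, on the retained-intron Tfrc-206 (39.4% ± 8.99), and that of Pklr on the 345-base Pklr-205 (58.9% ± 3.86). TPM of these genes rests on the length of the chosen transcript, so it depends on this assignment.

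The last question was how well the replicates matched. Levels were correlated over all genes, but those of single genes often differed by more than counting error. Gapdh had 2229.8 TPM in replicate 1 and 24671 in replicate 2, Actb 328 and 1385, Cdk1 8.53 and 73.2, and Hbb-bt 29.8 and 411. The Hbb-bt counts were fractional, at 504.25 and 12231.5, so reads shared with other genes may be part of its gap. In the other direction Spred1 had 13 and 3.95 TPM, Ccne1 644 and 214, and Lmo2 2383 and 964. The size of some gaps depended on the unit: by scaled counts Gapdh was 6.51-fold, Cdk1 4.24-fold, Actb 6.16-fold and Hbb-bt 14.7-fold higher in replicate 2, against 11.1-, 8.58-, 4.22- and 13.8-fold by TPM. For Ccne1 and Lmo2 replicate 2 had 0.484 and 0.595 times the level of replicate 1 by scaled counts, against 0.332 and 0.405 by TPM. 4595 of 11230 genes passed the exact binomial test at an adjusted p under 0.05 and 1.5-fold, 2700 higher in replicate 2 and 1895 in replicate 1. This test compares these libraries, not conditions.

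Of the 5 genes with the largest fold in each direction, among called genes with a mean of at least 5 TPM, 6 of 10 were annotated as processed pseudogenes, copies whose reads can be divided differently in each library. The others, Gm28037, Hist3h2a, Pagr1b and mt-Co3, also had counts that were not whole, a sign of shared reads. The folds below were therefore not separated from reads moved between genes. Highest in replicate 2 were Gm28037, Gm10231, Hist3h2a and Pagr1b, with no counts in replicate 1 and 6916, 2720.2, 1384 and 1305 in replicate 2, at least 1398-, 549.7-, 279.7- and 264-fold against a floor of 3 counts, with lower exact 95% limits of 1136, 447, 227 and 214. Gm10132 had 1 and 5071 rounded counts, a ratio of 3074 with an exact 95% interval from 552 to 121451. Highest in replicate 1 were the pseudogenes Gm12751, Gm2810 and Rps12l1, at least 187-, 165- and 65.4-fold against the same floor, with lower exact limits of 152, 133 and 52.4. They were followed by mt-Co3, a mitochondrial cytochrome oxidase subunit, at 47.8-fold (261 against 8.95 counts), and by Rpl38-ps2, at 19.8-fold, whose exact 95% interval ran from 4.91- to 173-fold.

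Across the 9277 genes with 1 TPM or more in either library, Pearson's r of log2(TPM + 1) was 0.929 and Spearman's rho 0.924; these are correlations across genes, which are not independent replicates. Among 4245 genes with 1000 or more counts in each library the SD of the log2 ratio of scaled counts was 0.69, where counting error alone gives 0.04, a level that separately prepared libraries commonly exceed. The biological coefficient of variation from edgeR was 0.394, or 0.233 as the median gene-wise estimate of DESeq2. At 1 TPM or more in both libraries, 8535 genes were detected, 8062 of them nuclear protein-coding.

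**Figure D3:**
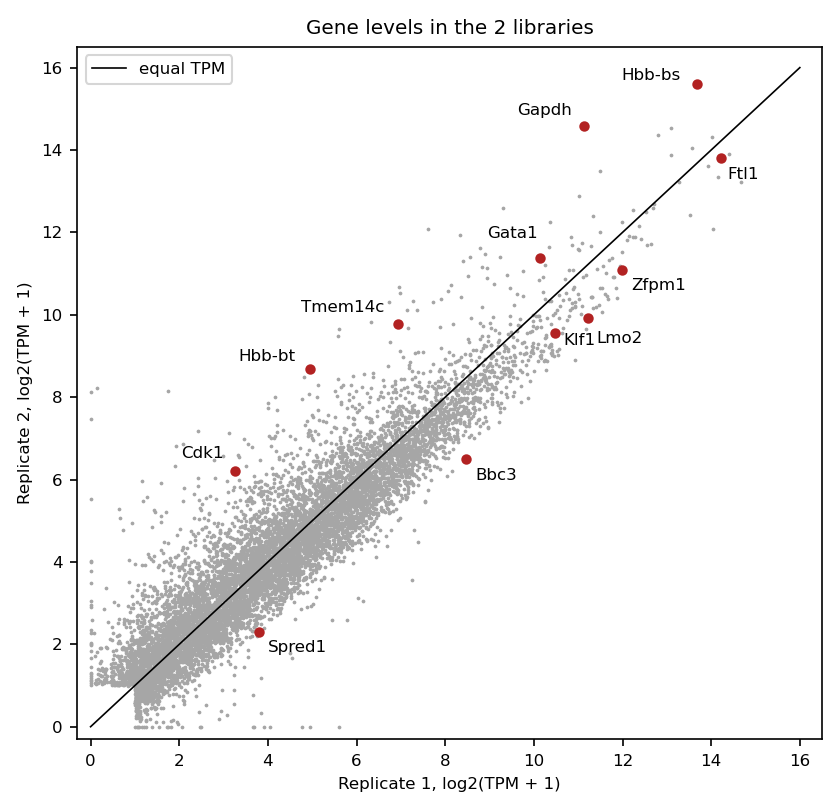
Each gene with 1 TPM or more in either library, replicate 1 on the horizontal and replicate 2 on the vertical axis, both as log2(TPM + 1), with a line of equal TPM and named genes in red. Gapdh, Hbb-bt, Tmem14c and Cdk1 lie well above the line, and Bbc3, Lmo2 and Spred1 below it.

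A small number of genes made up much of each library. The 10 highest genes held 19.2% ± 3 of TPM, the 100 highest 46.8% ± 3.3 and the 1000 highest 79.2% ± 0.59. Globins held 3.02% in replicate 1 and 8.06% in replicate 2. Genes named Rpl or Rps held 11.4% and 17.8%. Replication-dependent histone genes held 4.57% ± 1.19, and mitochondrially encoded genes only 0.267% ± 0.0714. All these shares were smaller as shares of counts not divided by length, where globins held 1.87% ± 1.3. Outside ribosomal proteins and the globins, ferritins and Gapdh already given, the highest nuclear protein-coding genes included the histone genes Hist1h2ap (18386 ± 2691 TPM), Hist1h2ad (10544 ± 8783), Hist1h2ao (8669.7 ± 4439.9) and Hist1h2af (4596 ± 1285), near-identical copies whose single values are uncertain. How well polyA selection captures these histone messages was not tested, so their share and rank are not read as message abundance. Ptma, a chromatin-associated acidic protein gene, stood at 14524 ± 3279 TPM, aldolase Aldoa at 5393 ± 811, profilin Pfn1 at 4875 ± 2165 and the nuclear transport GTPase Ran at 4649 ± 1857 TPM. Hdgf, Fau, Cox6a1, Epn1 and Eif4g2 stood at 3971 ± 563, 3494 ± 857, 3487 ± 787, 3052 ± 574 and 2936 ± 508 TPM, and Zfpm1 was the only member of the erythroid factor list among these 20 genes.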

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

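All alternatives but the GC trend were planned ahead. Leaving out each replicate gave detected genes of 8905 to 8907 (from 8535), a count of 13 of 22 lists above random lists, most of whose genes are silent, so this count says little of stability, and genes with several isoforms of 16 to 19 (from 14). The correlation, library difference, coefficient of variation, pair criterion and list difference need both libraries, so no value without a replicate exists for them. The correlation of 0.929 became 0.979 with no filter, where undetected genes enter, and 0.888 at 5 TPM, for which the cause was not tested. Genes called fell from 4595 to 2409 at a fold of 2, by construction. The coefficient of variation was 0.233 with the DESeq2 gene-wise median; the cause was not tested.

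List medians that moved by more than the SD between replicates were, in FPKM, iron 32.9, progenitor 0.81, S phase 46.9, cell cycle regulators 21.4, autophagy 50.1, stress 55.9 and estrogen response 0.0125, and, without mitochondrial and globin genes, cell cycle regulators 27.1 and estrogen response 0.0162. Both units rescale each library by a constant, so all medians above 0 shift by construction, and these pass the SD because theirs is small.

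With each replicate left out, with causes not tested, medians were haem synthesis 164 to 211, membrane 30.3 to 59.7, mitosis 48.3 to 73.2, cell cycle regulators 30.1 to 31.6, autophagy 57.3 to 69.4, cytokine signalling 24.7 to 36, estrogen response 0.01 with either left out, stress 50.5 to 57 and housekeeping 81.8 to 116. Late erythroid medians ran from 28.6 to 60.6 and globins from 0.36 to 2.11, within the SD only because it is taken from the same libraries. As shares of counts, globins held 1.87%, ribosomal proteins 5.71%, histones 1.22%, mitochondrial genes 0.178% and the 100 highest genes 32.8%, all lower than in TPM, where the only change is division by length. Cdkn1b over Cdkn1a went from -0.10 to 1.5 on the log2 scale in counts not divided by length, where it met the criterion. Ftl1 over Fth1 also changed sign, from 0.26 to -0.25, within its range. For these abundant genes the only change is again division by length. 16 pairs passed with those counts, as Zbtb7a/Bcl11a, Cdkn1b/Cdkn1a and Car2/Car1 were gained and Slc2a1/Slc2a3 (0.34) and Bnip3l/Bnip3 (-0.05) lost, and 15 with FPKM. Of the 4 lists beyond the percentile bounds in the replicate comparison, 4 stayed outside with scaled counts and 3 after the GC trend was removed, a setting chosen after seeing the data. Depth limits genes with few counts, such as the embryonic globins.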

Other observations

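Glycolysis genes, a group chosen after the data were seen, showed 1 dominant form at some steps and several at others. 18 of 27 genes passed 1 TPM in both libraries. Aldoa stood at 5393 ± 811 TPM (SD, n = 2) and Aldoc at 5.67 ± 6.15. Ldha stood at 2889 ± 532 TPM with Ldhb and Ldhc at 0 counts, and Eno1 stood at 782 ± 768 TPM beside Eno1b at 168 ± 113, with Eno2 at 0 counts and Eno3 at 3.11 ± 0.608 TPM. Eno1 and Eno1b had fractional counts, 13407.4 and 4328.92 in replicate 1, a sign of shared reads, so their single values are uncertain. Of the phosphofructokinase genes, Pfkl stood at 285 ± 113, Pfkm at 70 ± 27.8 and Pfkp at 72.5 ± 79.1 TPM. Both pyruvate kinase genes were expressed, Pkm at 1132 ± 381 and the red cell and liver form Pklr at 278 ± 159.5 TPM. Several steps were higher in replicate 2: Gapdh had 2229.8 and 24671 TPM, Tpi1 337 and 2547, Gpi1 492 and 1907, and Eno1 239 and 1324. Pgk1 had 54.4 and 26 TPM and Pfkl 365 and 204.

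Among DNA methylation and histone enzymes, also chosen after the data were seen, the maintenance methyltransferase Dnmt1 stood at 118 ± 23.9 TPM and its partner Uhrf1 at 70.8 ± 25.1 TPM. Dnmt3b had 7.08 ± 4.14 TPM, and Dnmt3a had 0 and 1 counts. Of the Tet dioxygenases, Tet3 stood at 33.9 ± 9.85 TPM, Tet2 at 1.44 ± 0.0849 TPM and Tet1 at 0 counts. Hdac7 led the deacetylases at 139.8 ± 83 TPM, followed by Hdac5 at 88.7 ± 21.5 TPM, and Hdac9 had 0 counts. Ezh2 stood at 28.4 ± 7.38 TPM and Ezh1 at 2.43 ± 1.36 TPM.

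Some abundant genes rested on transcripts other than the full-length coding one, named here after their values were seen. Hbb-bs-202, annotated as retained intron (chromosome 7, 103826728 to 103827725), held 98.2% and 99.9% of Hbb-bs TPM, against 1.84% and 0.07% for the coding transcript of 3 exons. Its deposited length was 549 bases. The M21 models of both transcripts, which give the coordinates and exons, differ from the deposited ones in length. Gapdh-206, also annotated as retained intron, held 13.2% of Gapdh in replicate 1 and 69.9% in replicate 2. The 229-base Ran-203 held 92% and 87.2% of Ran TPM. Transcripts annotated as retained intron held 11.4% of TPM in replicate 1 and 17.6% in replicate 2. Gm26917 and Gm42418, annotated as lincRNA and next to each other on GRCm38 (chromosome 17, 39843013 to 39846341 and chromosome 17, 39846958 to 39848788), together held 7.31% of all counts in replicate 1 and 4.18% in replicate 2. Whether these reads come from ribosomal RNA was not tested, so the share is not read as expression of lincRNA.

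The tests below were all chosen after the results were seen, and with 1 group no biological explanation was tested. The first pattern is the spread between the libraries, an SD of the log2 TPM ratio of 0.75 over 4201 genes with 1000 or more counts in each. The ratio fell with the GC content of the first 200 bases (Spearman's rho -0.325 across genes, which are not independent replicates). It hardly fell with that of the whole transcript (-0.0401). By this correlation the GC content of the first bases may contribute. Yet 91.6% of the SD was left once trends with GC content were removed, which argues against these trends as the whole cause. Genes beyond 2-fold fell from 766 to 502. This fall does not separate GC content from an offset of the ratio, which removal of the trends can also take away. The median ratio was negative in every bin of that GC content, at -0.0812 in the lowest and -0.611 in the highest. By scaled counts, with no trend removed, 12.8% of 4245 genes were beyond 2-fold. Genes whose counts were whole within 0.005 in both libraries, a sign of no shared reads, still had an SD of 0.712, against 0.978 for the others, and the 938 of them with 1 annotated transcript had 0.663, so neither shared reads nor isoform assignment accounts for most of it. A difference in the cells, in RNA handling or in library preparation stays open, as no label separates them.

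The other pattern is that subunits of the same complex differ widely within each library. Proteasome subunits ran from 1.22 TPM for Psmd10 to 451 TPM for Psmb4, and the 75 of 77 ribosomal protein genes with a GC value, which leaves out Rpl18 at 18410.4 ± 4490.2 TPM and Rpl13a, from 5.58 TPM for Rpl29 to 16304 TPM for Rplp1. A candidate explanation is GC content as a contributor: across genes, which are not independent replicates, Spearman's rho of GC content and TPM was 0.814 and 0.779 in the libraries for proteasome subunits (permutation p = 1e-05, the smallest it can give, adjusted 2e-05), and the lowest of 8 values over 4 complexes was 0.362, for NADH dehydrogenase subunits (permutation p = 0.0304, adjusted 0.0304). For ribosomal proteins it was 0.407 and 0.418 over subunits. This set was narrowed after the values for all names beginning Rpl or Rps (0.289 and 0.273) had been seen. In that wider set the 20 genes with whole counts gave 0.0301 and -0.116, against a mean of 0.594 for the 10 subunits with whole counts. The wider set also holds genes that do not encode ribosomal proteins, such as the kinase genes Rps6ka1 and Rps6kb1. Its values therefore do not describe ribosomal proteins alone, and the subunit values rest on a set chosen after the data were seen. With whole counts only, the other complexes kept means of 0.798, 0.596 and 0.456. Against shared reads or length as the whole cause in the proteasome, the fold between the 90th and 10th percentile, 66.6, was 83.7 among subunits with whole counts and 64 in counts not divided by length. The other complexes were mixed for shared reads: with whole counts only, the fold fell from 121 to 26.7 for ribosomal proteins and from 63.6 to 39.2 for mitochondrial ribosomal proteins, and rose from 31.8 to 46.7 for NADH dehydrogenase subunits, so shared reads may widen part of the ribosomal spread.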
